A study of Homo sapiens with 10 samples.

How the data were processed

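Transcript levels were measured by RNA sequencing in 10 libraries of a single cell line. Per the labels' protocols, total RNA of KYSE-410 cells was extracted with a column kit that included DNase treatment, its quality was checked on a Bioanalyzer, and libraries were made with the Ovation Solo RNA-Seq System. Per the submitters' processing notes, the tools were STAR 2.5.3a (a read aligner) and HTSeq (a read counter, version not given in the sources used here), with the hg38 genome build. The annotation, the counting rules and whether strand was used are not given in the sources used here.

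The authors deposited 1 table of CPM (read counts scaled to a common library total) for 58302 Ensembl gene IDs in 10 libraries. CPM values are not read counts, and each library's values summed to the total that CPM defines, within rounding. Of the IDs, 58039 were matched to GENCODE 29 on GRCh38, from which chromosome positions, exon lengths and gene types were taken, and 263 were not matched. Symbols are those of the table, some of them older (CTGF for CCN2, CYR61 for CCN1). The values of every library were whole multiples of about 0.05 CPM (100.0% of values within 0.05 of a step). That pattern would arise if reads had been scaled to a common total near 20.01 M reads and rounded up before division, a step inferred from the values and recorded in no source used here. On that inference the libraries held 18.37 to 26.32 M reads assigned to genes, with 21.52, 21.98 and 20.79 M in the DMSO libraries of the K149 arm, 23.04, 20.9 and 19.81 M with K149, 18.37 and 20.78 M in the DMSO libraries of the AS1949490 arm, and 26.32 and 26.17 M with AS1949490. At this depth, 1 read was worth about 0.05 CPM, so values below 1 CPM rested on few reads. In 2 libraries (K149 replicate 3 and DMSO replicate 1 of the AS1949490 arm) the lowest step was empty, as the inferred scaling with factors above 1 (1.0095 and 1.0885) and rounding up would leave it. On that inference, each value in these 2 libraries matched 1 whole number of reads, and in the other 8 the reads were known to within 1 read. EdgeR was also run on those 8 alone, which leaves 1 library in the DMSO group of the AS1949490 arm.

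Overlapping genes appeared to be counted for the same reads without regard to strand: SRXN1 and the overlapping AL121758.1 had mean values of 275.8 CPM each, and DDIT4-AS1, antisense to DDIT4, had 53.48 CPM. Of 240 named genes checked, 70 shared any exon base with another gene and 11 shared at least 25% of their exon bases. Those 11 are called uncertain where they are named.

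Groups came from the sample titles, except that the title of DMSO replicate 3 of the K149 arm names no arm and its library name was used. The library names of the AS1949490 arm carry other replicate numbers than the titles. The labels do not state that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 1.49 to 9.7), so none was treated as a duplicate.

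The design fixed before the data were examined assumed read counts and named edgeR as the test. Because the table holds CPM, its stated fallback was used: limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend) on log2(CPM + 1), with all 10 libraries and 4 group means in 1 fit. Genes with a group mean of at least 1 CPM in at least 1 group were tested (17837 genes). P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was a call. Each log2 fold is on the log2(CPM + 1) scale, which understates changes of low genes, and is given ± its standard error (SE). The contrasts were K149 against its DMSO (3 libraries each), AS1949490 against its DMSO (2 each), the difference of these effects (K149 minus AS1949490), and the DMSO libraries of the K149 arm minus those of the AS1949490 arm. The last contrast shares its libraries with the difference of effects.

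Before the data were examined, 44 gene lists were fixed from textbook knowledge, of which 41 had at least 5 tested members. They cover the cell cycle, stress responses, growth signalling, metabolism, organelles, squamous and other cell types, and RNA quality. Lists were tested with limma's camera, which compares the members' moderated statistics with those of all other genes, at a preset correlation of 0.01 between members. Camera with the correlation estimated from these libraries was an alternative, as was fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. P-values of lists were adjusted over the 41 lists of a contrast. Beside the counts over all genes tested, members were counted with p adjusted over the list alone.

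Genes were named by a rule fixed in advance. It took INPPL1, then the 8 genes with the largest fold in each direction for each inhibitor (adjusted p under 0.05, mean of at least 5 CPM in the arm, treated and control libraries not overlapping, no clone-based, antisense, small-RNA or Y-linked genes). It also took the 4 members with the smallest adjusted p of each called list. As run, only members that moved in the direction of the call were taken, so the members named share that direction by choice. Further, it took 2 members each of up to 4 further lists, 5 genes in each direction of the difference, and 5 for each class of overlap. A few genes that this rule takes are not reported here. The 8 genes in each direction that set the DMSO libraries apart were chosen after their values were seen, as were the members named of lists that were not called, other than those of the 5 lists of p53, FOXO, NF-kB, cholesterol and squamous differentiation genes.

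Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a stricter filter, TMM, RLE and upper quartile scaling, the libraries of an arm alone, a robust spread, a replicate block, DESeq2 1.42.0 on the inferred reads, and leaving out each library in turn. The fixed design had TMM as its main scaling and library totals as the alternative, and for CPM these changed places. Added after the data were seen were edgeR 4.0.16 on the inferred reads (all 10 libraries, and the 8 whose lowest step was not empty) and a crossed replicate block.

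The tests were checked on simulated reads made from the real library sizes and gene means. For K149 against DMSO (17510 genes tested), limma called 83.6% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold, and 10 of 17279 unchanged genes. For AS1949490, it called 62.7%, 92.5% and 100%, and 9 of 17310 unchanged genes. For the difference, it called 61.1%, 88.5% and 99.2%, and 16 of 17089. Read totals inferred from simulated steps were off by at most 0.26%. In the simulated K149 contrast and the simulated difference, camera called only the 1 list that had been shifted. In the simulated AS1949490 contrast, where none was shifted, it called none. Reads were drawn for each gene independently, so members of a list were not correlated, and far fewer genes changed than in the data. The simulation therefore cannot show how often camera calls lists whose members are correlated.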

Results

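Transcript levels were measured in KYSE-410, an established cell line from a human squamous cell carcinoma of the esophagus, 48 h after 1 of 2 inhibitors of SHIP2 was added. SHIP2, the product of INPPL1, is a phosphatase that removes a phosphate from the lipid messenger made by phosphoinositide 3-kinase (PI3K). K149 was given at 2 µM and AS1949490 at 20 µM, and each inhibitor had its own control libraries from cells given the solvent, DMSO (0.1%). The K149 arm had 3 DMSO and 3 K149 libraries, and the AS1949490 arm had 2 DMSO and 2 AS1949490 libraries. Doses and control libraries differed between the arms, so each effect was taken within its arm. Depth, inferred from the steps of the CPM values, ran from 18.37 to 26.32 M reads per library, and the AS1949490 libraries (26.32 and 26.17 M) were deeper than their controls (18.37 and 20.78 M). The first principal component held 60.6% of the variance and placed K149 libraries between -64.8 and -58.6, the DMSO libraries of that arm between -0.6 and 0.1, AS1949490 libraries at 28.5 and 29, and their DMSO libraries at 67.0 and 62.6. The second held 29% and placed the DMSO libraries of the K149 arm between 48.4 and 48.8 and all other libraries between -30.2 and -13.8.

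The gene of the drug target was higher with both inhibitors. INPPL1 (ENSG00000165458, GRCh38 chromosome 11, 72223701 to 72239105, plus strand) rose from 113.4 ± 9.8 CPM in DMSO to 173.6 ± 9.8 CPM with K149 (SD, n = 3 each), a log2 fold of 0.61 ± 0.07 (SE, limma adjusted p = 2.38e-06). With AS1949490 it rose from 135.7 ± 7.99 to 198.4 ± 8.79 CPM (SD, n = 2 each), a log2 fold of 0.55 ± 0.08 (limma adjusted p = 0.000122). The effects differed by 0.07 on the log2 scale (limma adjusted p = 0.648 for the difference). Of the 40 tested kinases and phosphatases of phosphoinositides, 24 rose and 5 fell with K149 (26 and 6 adjusted over the list alone), and 27 rose and 4 fell with AS1949490 (27 and 6). Camera called this list higher with K149 (median log2 fold 0.26, adjusted p = 0.00839) and with AS1949490 (0.31, adjusted p = 0.00552), and lost both calls with an estimated correlation (adjusted p = 0.632 and 0.497). PIP4K2C, which encodes a phosphatidylinositol phosphate kinase, rose with both inhibitors (log2 folds 0.69 ± 0.04 and 0.74 ± 0.05). PIK3R3, a regulatory subunit of PI3K (1.22 ± 0.06), PIK3C3 (0.90 ± 0.07) and PIP5K1C (0.66 ± 0.06) were further leading members with K149. INPP4A (0.82 ± 0.07), PIK3C2B (1.01 ± 0.09) and PIK3R1 (0.80 ± 0.09) were those with AS1949490.

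**Figure D1:**
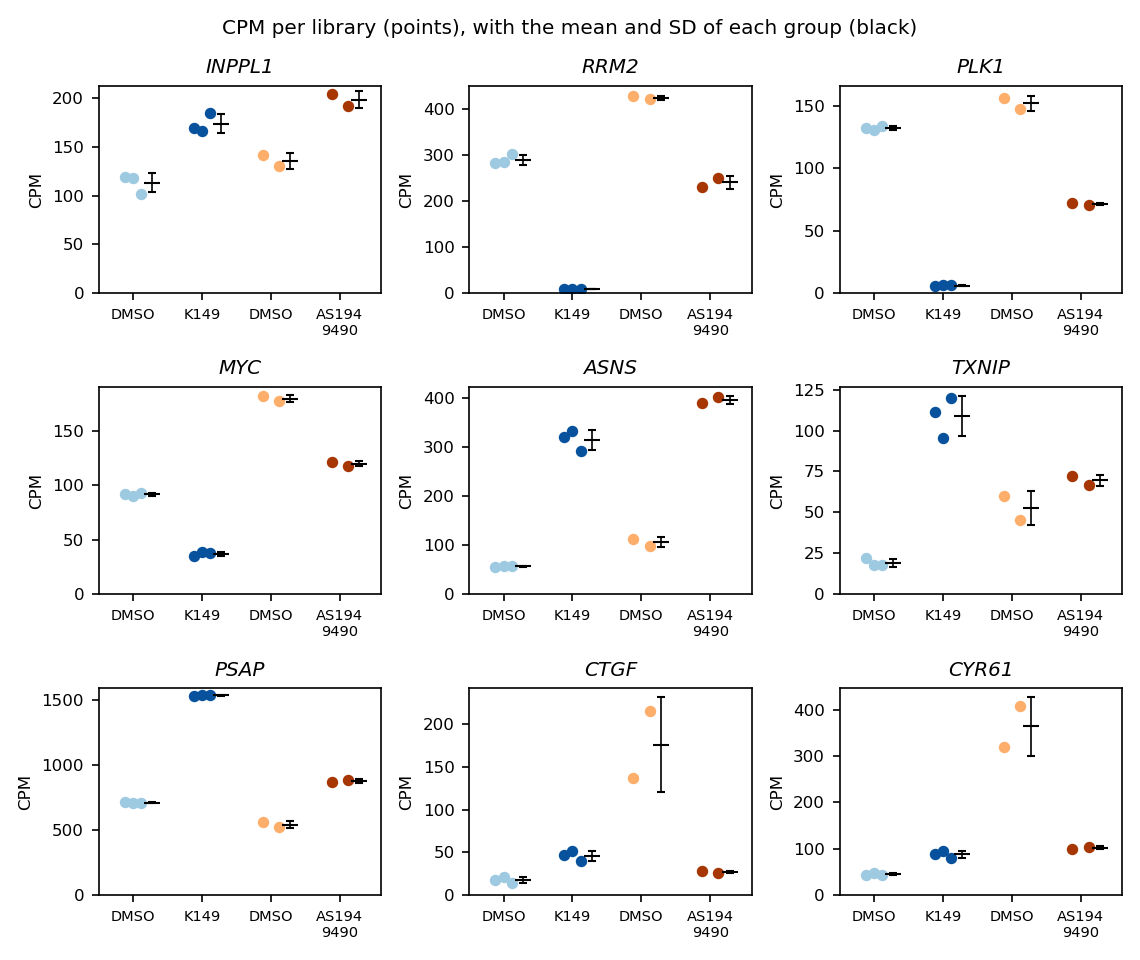
CPM of 9 genes in each library (points, y axis in CPM starting at 0), with the mean and SD of each group in black, for DMSO and K149 (blue, n = 3 each) and DMSO and AS1949490 (orange, n = 2 each). INPPL1 rose in both arms, RRM2 and PLK1 fell further with K149 than with AS1949490, and CTGF and CYR61 rose with K149 and fell with AS1949490.

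With K149, genes of cell division fell together. All 44 measured genes of G2/M and mitosis and all 38 of G1/S and DNA replication fell (the same counts adjusted over the list alone), with median log2 folds of -3.86 and -3.27. RRM2, a subunit of the reductase that supplies deoxynucleotides, fell from 289.9 ± 10.3 to 8.91 ± 0.598 CPM (SD, n = 3 each), a log2 fold of -4.88 ± 0.06 (limma adjusted p = 4.01e-16). The mitotic kinase PLK1 fell from 132.6 ± 1.63 to 5.946 ± 0.458 CPM (-4.27 ± 0.06) and MCM2, of the replicative helicase, from 151.6 ± 2.92 to 9.476 ± 0.203 CPM (-3.86 ± 0.05). The leading members also held MCM5 (-3.86 ± 0.06), the spindle genes TPX2 (-3.92 ± 0.04) and PRC1 (-4.21 ± 0.05), BIRC5 (-4.17 ± 0.06), and TYMS (-4.26 ± 0.05), which shares 39.1% of its exon bases with the antisense ENOSF1 and is uncertain. Camera called both lists lower (adjusted p = 7.1e-33 and 3.69e-28) and kept both calls with an estimated correlation (adjusted p = 0.0246 and 0.00344).

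Genes of amino acid and stress signalling, of lysosomes and of autophagy rose with K149. Of 34 targets of the integrated stress response, the ATF4-driven programme induced by amino acid shortage and other stress, 26 rose and 3 fell (27 and 3 adjusted over the list alone). CHAC1, which degrades glutathione, rose from 3.515 ± 0.0289 to 33.34 ± 3.67 CPM (log2 fold 2.92 ± 0.08), and ATF3 (1.96 ± 0.08) and STC2 (1.56 ± 0.05) rose too. ASNS, asparagine synthetase, rose from 56.75 ± 0.849 to 315.4 ± 20.3 CPM (2.45 ± 0.06) but is uncertain, since 44.6% of its exon bases lie in an overlapping gene. This list kept its call with an estimated correlation (camera adjusted p = 1.51e-06 preset and 0.0208 estimated). Of 36 lysosomal genes, 32 rose and 3 fell (median 0.64), led by PSAP (711.8 ± 3.89 to 1540 ± 3.69 CPM, log2 fold 1.11 ± 0.04), GPNMB (1.60 ± 0.07), the sialidase NEU1 (1.65 ± 0.07) and TPP1 (1.11 ± 0.06). Of 25 autophagy genes, 22 rose and none fell by limma (median 0.65), among them TP53INP2 (3.24 ± 0.08), GABARAPL1 (2.02 ± 0.06), the cargo receptor SQSTM1 (1.46 ± 0.06) and MAP1LC3B (1.27 ± 0.06). Both counts were the same adjusted over the list alone. With an estimated correlation, the lysosomal and autophagy lists lost their calls (adjusted p = 0.0814 for both).

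Of 25 targets of FOXO factors, which AKT keeps out of the nucleus, 20 rose and 4 fell with K149 (median 0.73, camera adjusted p = 0.000138, 0.262 with an estimated correlation). TXNIP rose from 19.21 ± 2.5 to 109.0 ± 12.4 CPM (log2 fold 2.44 ± 0.11), and FBXO32 (1.47 ± 0.06), SESN3 (2.08 ± 0.10) and PIK3IP1 (1.75 ± 0.09) rose. Of 32 NRF2 targets, the oxidant response, 22 rose and 3 fell (median 0.46, camera adjusted p = 0.000313, 0.632 with an estimated correlation), with TXNRD1 (1.72 ± 0.05), ABCC3 (1.10 ± 0.06), OSGIN1 (1.79 ± 0.10) and the uncertain SRXN1 (1.65 ± 0.07). Of 27 genes of the TGF-beta response, 20 rose and none fell by limma (median 0.46, adjusted p = 0.000304, 0.401 estimated). They included ID2 (1.37 ± 0.05) and PMEPA1 (0.87 ± 0.06). The list of the immediate early and dissociation response, which also marks handling stress, is called immediate early genes here. Of its 26 genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone). Its median was 0.49 (camera adjusted p = 0.000342, 0.401 with an estimated correlation). Members that rose included ATF3, KLF4 (1.07 ± 0.07), CYR61 (0.95 ± 0.08) and HSPA1B (0.73 ± 0.06), which is also in the heat shock list. Of 14 replication-dependent histone genes, 10 rose (10 rose and 1 fell adjusted over the list alone; median 0.97, adjusted p = 0.00148, 0.0818 estimated), with HIST1H2AC (2.60 ± 0.07), HIST1H2BC (2.11 ± 0.10), HIST1H2BD (1.96 ± 0.11) and HIST1H1C (1.19 ± 0.08). These histones belong to a family of near copies and are uncertain, and without the filter on low values the list's call was lost (median 0.02, adjusted p = 0.068), and with DESeq2 the call held with a median of 0.003. Of 11 targets of the AHR xenobiotic receptor, 8 rose and 1 fell (median 0.48, adjusted p = 0.047, 0.247 estimated), with TIPARP (1.16 ± 0.05), CYP1B1 (1.69 ± 0.09), NQO1 (0.95 ± 0.07) and ID3 (0.70 ± 0.07). The AHR call was lost when any of 6 libraries was left out: DMSO replicate 1 or 2 of the K149 arm (adjusted p = 0.0513 and 0.0576), K149 replicate 2 or 3 (0.063 and 0.0538), or AS1949490 replicate 1 or 2 (0.0512 for both).

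Genes of ribosome production fell with K149 by smaller amounts. Of 38 MYC targets and ribosome biogenesis genes, 37 fell and 1 rose (median -0.68, camera adjusted p = 3.03e-12, 0.0814 with an estimated correlation). MYC itself fell from 92.0 ± 1.41 to 37.07 ± 1.62 CPM (log2 fold -1.29 ± 0.05), with DKC1 (-1.25 ± 0.06), MRTO4 (-1.42 ± 0.06) and NOP56 (-1.33 ± 0.07). Of 75 ribosomal protein genes, 70 fell (71 adjusted over the list alone; median -0.36, adjusted p = 1.14e-09, 0.632 estimated), led by RPL3 (-0.73 ± 0.06), RPLP0 (-0.61 ± 0.06), RPL12 (-0.61 ± 0.07) and RPSA (-0.61 ± 0.07). Ribosomal protein genes held 2.26, 2.5 and 2.23% of CPM in the K149 libraries and 2.98, 3.03 and 3.06% in their controls. Of 31 proteasome genes, 24 fell (median -0.20, adjusted p = 0.00073, 0.666 estimated), with PSMC3 (-0.76 ± 0.07), PSMB2 (-0.55 ± 0.06), PSMB6 (-0.46 ± 0.07) and PSMC5 (-0.39 ± 0.07). Of 68 nuclear genes of oxidative phosphorylation, 36 fell and 3 rose (35 and 3 adjusted over the list alone; median -0.17, adjusted p = 0.0043, 0.723 estimated), with SDHA (-0.53 ± 0.04), UQCRC2 (-0.57 ± 0.05), ATP5G1 (-0.63 ± 0.07) and CYC1 (-0.48 ± 0.06). K149 replicate 2 stood apart on some of these lists, with per-library medians of -0.04 for oxidative phosphorylation, against -0.22 and -0.26 in replicates 1 and 3, and of -0.24 for ribosomal proteins, against -0.39 and -0.42. Its chi-square per degree of freedom was 7.72 against replicate 1 and 9.01 against replicate 3, where replicates 1 and 3 gave 2.94.

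Single genes with the largest folds with K149, taken on CPM + 1 as the ratio of geometric means, included markers outside these groups. TP53INP2, which takes part in autophagosome formation, rose 9.46-fold on that scale, from 7.279 ± 0.796 to 77.11 ± 1.86 CPM (SD, n = 3 each, limma adjusted p = 5.06e-13). MAP1B (8.11-fold), CHAC1 (7.58-fold), the p53 target TP53INP1 (7.55-fold), ERV3-1 (6.76-fold), the pro-apoptotic BMF (6.35-fold), the stress cytokine GDF15 (6.17-fold) and HIST1H2AC (6.07-fold) followed. KRT13, a keratin of stratified esophageal epithelium, had a fold of 0.0307 on that scale, falling from 415.2 ± 3.78 to 12.01 ± 3.13 CPM. The other largest falls were in RRM2 (fold 0.034), MCM10 (0.0344), MYBL2 (0.0355), CDCA7 (0.0368), FAM111B (0.0368), CDC45 (0.039) and DLGAP5 (0.044), genes of replication and mitosis or expressed with them.

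K149 changed members of lists that camera did not call. Of 29 p53 targets, 15 rose and 8 fell (median 0.39, adjusted p = 0.181), with CDKN1A, the cell-cycle inhibitor p21, higher (1.60 ± 0.06) and DDB2 lower (-1.80 ± 0.07). Of 25 cholesterol synthesis genes, 8 rose and 11 fell (median -0.12), with SC5D higher (1.15 ± 0.06) and FDPS lower (-1.11 ± 0.06). Of 23 squamous differentiation genes, 6 rose and 10 fell (median -0.06), including KRT13 and the protease KLK6 (-1.19 ± 0.05). Of 28 NF-kB and cytokine genes, 7 rose and 5 fell (median -0.03), including TNFAIP2 (-0.77 ± 0.05) and NFKB1 (-0.71 ± 0.06). Medians of the remaining uncalled lists were -0.26 for heat shock, 0.21 for the unfolded protein response, 0.24 for EGFR family receptors and ligands, 0.27 for MAPK-ERK output, -0.64 for metallothioneins, 0.26 for matrix proteases, 0.37 for YAP and TEAD targets, 0.20 for antigen presentation, 0.22 for hypoxia and glycolysis, and 0.21 for basal squamous genes. They were -0.09 for interferon-stimulated genes, 0.13 for apoptosis regulators, -0.06 for senescence-associated factors, -0.31 for LXR targets, 0.09 for mesenchymal genes, -0.03 for mitochondrially encoded genes, 0.05 for fatty acid synthesis, 0.10 for fatty acid oxidation and 0.02 for nuclear-retained RNA. Markers of columnar epithelium (-0.27) and immune cells (-0.37, 5 tested) were not called either. Fibroblast, endothelial and stress keratin lists had under 5 tested members and medians of 0.05, -0.58 and -0.89. Camera's direction and the median differed in sign for fatty acid synthesis and for nuclear-retained RNA, and the mean and the median for fatty acid synthesis, fatty acid oxidation and LXR targets. With DESeq2, 7 of these lists passed: p53 targets (adjusted p = 0.00205), the unfolded protein response (0.00835), squamous differentiation (0.0106), heat shock (0.0198), EGFR family genes (0.0221), YAP and TEAD targets (0.0329) and matrix proteases (0.0416). With no filter on low values, heat shock (0.00511), the unfolded protein response (0.0188), EGFR family genes (0.0188), MAPK-ERK output (0.0237) and YAP and TEAD targets (0.036) passed. Heat shock also passed with edgeR (0.0287) and a pseudocount of 5 (0.0437), and heat shock, the unfolded protein response and YAP targets with edgeR on 8 libraries (0.0363, 0.0294 and 0.0294). The list of nuclear-retained RNA, a sign of RNA quality, had per-library medians of 0.94 in K149 replicate 1 and -0.11 and -0.03 in replicates 2 and 3.

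By limma, 11837 of 17837 genes tested changed with K149, of which 6386 rose and 5451 fell, and 590 rose and 992 fell at least 2-fold. All 3 K149 libraries lay above all 3 DMSO libraries for 6722 genes and below them for 5810, where chance gives 10% of genes. Without K149 replicate 1, which stood apart on nuclear-retained RNA, 10919 genes changed and camera called 16 lists. With all libraries camera also called 16 of 41, 10 higher and 6 lower, of which 3 kept their call with an estimated correlation.

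**Figure D2:**
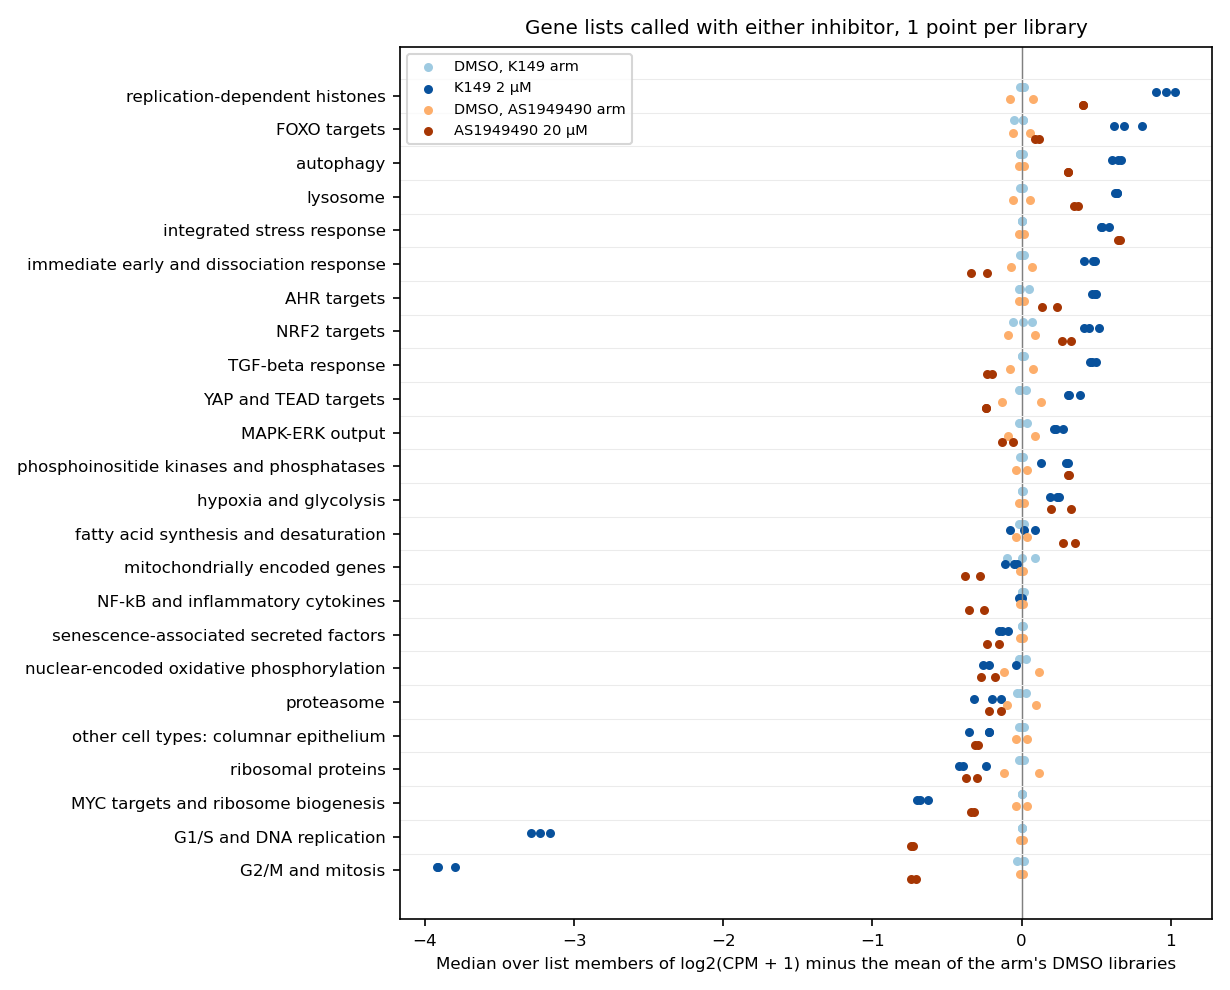
Median over the members of each list of log2(CPM + 1) minus the mean of the arm's DMSO libraries (x axis), with 1 point per library, for the lists called by camera with either inhibitor. The cell-cycle lists lay near -3 to -4 with K149 and near -0.7 with AS1949490, and the TGF-beta, immediate early and YAP lists lay above 0 with K149 and below 0 with AS1949490.

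With AS1949490, genes of the integrated stress response rose and genes of cell division fell. Of 34 integrated stress response targets, 29 rose and 2 fell (the same adjusted over the list alone), with a median log2 fold of 0.65 (camera adjusted p = 2.18e-08, kept with an estimated correlation at 0.00933). PSAT1, of serine synthesis, rose from 105.8 ± 4.05 to 302.3 ± 1.66 CPM (SD, n = 2 each), a log2 fold of 1.51 ± 0.06 (limma adjusted p = 6.26e-09), and VLDLR rose by 1.67 ± 0.10. ASNS (106.0 ± 10 to 397.1 ± 8.52 CPM, 1.90 ± 0.07) and DDIT4 (1.74 ± 0.07) led the list but are uncertain, DDIT4 sharing 41.2% of its exon bases with its antisense gene. Of 38 G1/S genes 36 fell (37 adjusted over the list alone), and of 44 G2/M genes 39 fell (40), each list with a median of -0.73. Leading members were MCM2 (-1.06 ± 0.06), MCM7 (-1.03 ± 0.06), MCM5 (-1.13 ± 0.07), TPX2 (-0.89 ± 0.06), PLK1 (-1.08 ± 0.07), CDC20 (-1.13 ± 0.08), BIRC5 (-1.01 ± 0.07) and the uncertain TYMS (-1.15 ± 0.06). G1/S kept its call with an estimated correlation (adjusted p = 2.76e-22 preset, 0.00646 estimated), and G2/M did not (5.24e-21 preset, 0.0764 estimated).

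Camera called 6 lists tied to growth factor, mechanical and cytokine signalling lower with AS1949490, in which many members had no call and some rose. Of 26 YAP and TEAD targets, 11 fell and 5 rose (12 and 5 adjusted over the list alone; median -0.24, camera adjusted p = 0.000411, 0.458 with an estimated correlation), with ANKRD1 (-2.55 ± 0.13), CYR61 (364.3 ± 63.7 to 102.1 ± 3.32 CPM, -1.81 ± 0.10), GADD45B (-1.55 ± 0.09) and AXL (-1.16 ± 0.07). Of 27 TGF-beta response genes, 14 fell and 3 rose (median -0.20, adjusted p = 0.000226, 0.318 estimated), with CTGF (-2.63 ± 0.19), THBS1 (-1.01 ± 0.07), BHLHE40 (-0.95 ± 0.07) and TGFBI (-0.77 ± 0.05). Of 26 immediate early genes, 13 fell and 3 rose (14 and 4; median -0.28, adjusted p = 0.000283, 0.318 estimated), with FOSB (-3.16 ± 0.18), JUNB (-1.21 ± 0.13), CYR61 and the uncertain IER3 (-0.89 ± 0.09). Of 28 NF-kB and cytokine genes, 15 fell and 6 rose (median -0.27, adjusted p = 0.00628, 0.154 estimated), with NFKB2 (-0.74 ± 0.07), RELB (-0.99 ± 0.10) and NFKBIA (-0.54 ± 0.06). Its call at the preset correlation held under the other scalings, filters, pseudocounts and gene tests and without each library, with medians from -0.551 (edgeR, 8 libraries) to -0.126 (no filter). Of 27 genes of MAPK-ERK output, 11 fell and 6 rose (11 and 7; median -0.09, adjusted p = 0.0373, 0.497 estimated), with EPHA2 (-0.87 ± 0.07), FOSL1 (-1.15 ± 0.10) and MYC (-0.58 ± 0.06). Per-library medians of the MAPK-ERK list with AS1949490 (-0.13 and -0.06) overlapped those of the arm's DMSO libraries (-0.09 and 0.09). Of 23 senescence-associated factors, 10 fell and 5 rose (median -0.15, adjusted p = 0.0373, 0.281 estimated), with LMNB1 (-0.95 ± 0.06), a nuclear lamina gene whose loss marks senescence, IGFBP4 (-1.09 ± 0.08), CXCL8 (-0.90 ± 0.16) and the uncertain PLAU (-0.43 ± 0.07). The MAPK-ERK call was lost with TMM or RLE scaling (camera adjusted p = 0.0534 and 0.0576), with larger medians in the same direction (-0.164 and -0.181). This call was also lost without DMSO replicate 2 of the arm, and the list's median was -0.134 without AS1949490 replicate 2. The senescence call was lost with TMM or RLE scaling (camera adjusted p = 0.0609 and 0.0682) and with edgeR (0.0576), with larger medians in the same direction (-0.234, -0.252 and -0.255). This call was also lost with the stricter filter (0.0586), without either DMSO replicate and without AS1949490 replicate 1. The list's median was -0.232 without AS1949490 replicate 2. The YAP median was -0.105 without DMSO replicate 2 (adjusted p = 0.0107).

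Lists of ribosomal, mitochondrial and proteasome genes and of columnar epithelium markers were lower with AS1949490. Of 75 ribosomal protein genes, 73 fell (74 adjusted over the list alone; median -0.33, camera adjusted p = 1.64e-15, 0.497 with an estimated correlation), with RPS2 (-0.55 ± 0.08), RPS9 (-0.49 ± 0.08), RPL12 (-0.51 ± 0.08) and RPS15 (-0.68 ± 0.11). They held 2.53 and 2.7% of CPM against 3.56 and 3.05% in DMSO. Of 38 MYC targets and ribosome biogenesis genes, 29 fell and 1 rose (median -0.33, adjusted p = 2.68e-08, 0.207 estimated), with FBL (-0.74 ± 0.08), MRTO4 (-0.69 ± 0.08) and NOP56 (-0.63 ± 0.08). Of 68 nuclear oxidative phosphorylation genes, 28 fell and 4 rose (27 and 4; median -0.22, adjusted p = 1.14e-05, 0.616 estimated), with ATP5J2 (-0.43 ± 0.08), NDUFC1 (-0.49 ± 0.10), NDUFS6 (-0.49 ± 0.10) and the uncertain NDUFB11 (-0.51 ± 0.09). Of 15 genes encoded in mitochondrial DNA, 10 fell and 2 rose (median -0.34, adjusted p = 0.00345, 0.58 estimated), with MT-CYB (-0.65 ± 0.07), MT-CO3 (-0.45 ± 0.07), MT-ATP6 (-0.44 ± 0.07) and MT-ND3 (-0.37 ± 0.06). Of 31 proteasome genes, 14 fell (12; median -0.19, adjusted p = 0.000421, 0.616 estimated), with PSMC3 (-0.49 ± 0.08), PSMB3 (-0.44 ± 0.09), PSMB6 (-0.39 ± 0.09) and PSMD2 (-0.30 ± 0.07). Of 12 tested columnar epithelium markers, 7 fell (8; median -0.26, adjusted p = 0.00164, 0.281 estimated). The members that fell were keratins that this squamous line also expresses at high levels, KRT18 (-0.61 ± 0.07), KRT8 (-0.47 ± 0.06) and KRT7 (-0.47 ± 0.06), and EPCAM (-0.23 ± 0.05) among them. The DMSO libraries of the arm lay apart on some of these lists, at 0.12 and -0.12 for ribosomal proteins and for oxidative phosphorylation and at 0.1 and -0.1 for the proteasome. Without DMSO replicate 1 the medians were -0.208, -0.088 and -0.078, and without replicate 2 they were -0.344 for oxidative phosphorylation and -0.289 for the proteasome, with each call kept.

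Lists that rose with AS1949490 besides the integrated stress response covered lysosomes, lipids, hypoxia and oxidants. Of 36 lysosomal genes, 25 rose and 2 fell (27 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 4.13e-05, 0.207 with an estimated correlation), with GPNMB (1.78 ± 0.08), TPP1 (1.04 ± 0.07), GAA (1.21 ± 0.08) and PSAP (0.70 ± 0.05). Of 25 autophagy genes, 14 rose (median 0.32, adjusted p = 0.00223, 0.309 estimated), with CALCOCO2 (0.99 ± 0.06), NBR1 (0.71 ± 0.06), SQSTM1 (0.70 ± 0.07) and TAX1BP1 (0.49 ± 0.05). Of 37 hypoxia and glycolysis genes, 22 rose and 3 fell (median 0.29, adjusted p = 0.00168, 0.281 estimated), with NDRG1 (107.3 ± 17.6 to 319.7 ± 15.5 CPM, 1.57 ± 0.09), P4HA1 (1.06 ± 0.09) and HK1 (0.65 ± 0.06). Of 18 fatty acid synthesis genes, 12 rose and 1 fell (median 0.32, adjusted p = 0.00651, 0.379 estimated), with ACSS2 (1.15 ± 0.07), the desaturase SCD (1.12 ± 0.11), ACSL1 (0.75 ± 0.06) and ME1 (0.51 ± 0.05). Of 32 NRF2 targets, 22 rose and 1 fell (median 0.30, adjusted p = 0.00297, 0.58 estimated), with ABCC3 (1.08 ± 0.07), CYP4F11 (1.38 ± 0.12), TXNRD1 (0.68 ± 0.06) and GCLC (0.72 ± 0.07), and the call was lost without DMSO replicate 2 (adjusted p = 0.0667). Of 14 histone genes, 7 rose and 1 fell (median 0.41, adjusted p = 0.0407, 0.281 estimated), with HIST1H2AC (1.92 ± 0.08), HIST1H1C (0.92 ± 0.10), HIST1H4I (1.04 ± 0.12) and HIST1H2BC (0.97 ± 0.13). The histone call was lost with a pseudocount of 5 (adjusted p = 0.0607), with DESeq2 (0.197, where the median was -0.43), and without K149 replicate 2, DMSO replicate 2 or AS1949490 replicate 1 (0.0618, 0.0619 and 0.0548), and with no filter on low values the median was -0.034.

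The largest single rise with AS1949490 by the naming rule, with folds again on CPM + 1, was in ALDH1L2, a mitochondrial folate enzyme, which rose 8.84-fold on that scale, from 5.546 ± 0.566 to 56.86 ± 4.66 CPM (SD, n = 2 each, limma adjusted p = 6.92e-09). The growth factor EPGN (6.56-fold), FAM129A (6.03-fold), the siderophore-binding LCN2 (5.05-fold), TLCD2 (4.34-fold), AHNAK2 (3.97-fold), PAPPA2 (3.97-fold) and TMC4 (3.93-fold) followed. FOSB had a fold of 0.112 on that scale, falling from 42.1 ± 12.1 to 3.747 ± 0.777 CPM, and CTGF one of 0.162, from 175.8 ± 55.6 to 26.86 ± 1.52 CPM. ANKRD1 (fold 0.17), FST, an inhibitor of activins (0.178), KRTAP2-3 (0.182), EGR3 (0.247) and DIO2, which activates thyroid hormone (0.254), were among the other largest falls. Of lists not called, 29 p53 targets had 12 members that rose and 6 that fell (median 0.11), with SESN2 (0.80 ± 0.08) and GDF15 (1.39 ± 0.14) higher. For 25 FOXO targets, 10 rose and 7 fell (median 0.08), with GADD45B (-1.55 ± 0.09) lower and CAT (0.84 ± 0.07) higher. For 25 cholesterol genes, 6 rose and 6 fell (median -0.08), with SC5D (0.59 ± 0.07) and TM7SF2 (0.83 ± 0.12) higher. For 23 squamous differentiation genes, 8 rose and 6 fell (median 0.14), with NOTCH3 (1.56 ± 0.10) higher and KLK6 (-0.82 ± 0.06) lower.

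Medians of the remaining lists that were not called with AS1949490 were 0.30 for interferon-stimulated genes (adjusted p = 0.06), 0.35 for fatty acid oxidation, 0.30 for basal squamous genes, 0.24 for EGFR family genes, 0.19 for AHR targets, 0.09 for nuclear-retained RNA, 0.23 for LXR targets and -0.07 for heat shock. They were -0.09 for mesenchymal genes, -0.08 for the unfolded protein response, 0.14 for metallothioneins, 0.10 for apoptosis regulators, 0.05 for matrix proteases, 0.06 for antigen presentation and -0.01 for immune markers. Fibroblast, endothelial and stress keratin lists had medians of -0.02, -0.16 and -0.43, with too few members for a test. Camera's direction was opposite to the sign of the median for FOXO targets, squamous differentiation, antigen presentation, nuclear-retained RNA, metallothioneins and immune markers, and the mean was opposite to the median for heat shock, the unfolded protein response, nuclear-retained RNA, metallothioneins and immune markers. The interferon list, with 20 members that rose and 5 that fell of 37, passed under 11 of 24 alternatives. These were TMM (adjusted p = 0.0477), RLE (0.0442) and upper quartile scaling (0.0491), DESeq2 (0.000704), edgeR (0.0218, and 0.0091 on 8 libraries), no filter (0.00309), a pseudocount of 5 (0.0445), and leaving out DMSO replicate 1 of the arm (0.0311), AS1949490 replicate 2 (0.0489) or K149 replicate 2 (0.0459). Basal squamous genes (0.00254 and 0.0201), fatty acid oxidation (0.00254 and 0.0378) and EGFR family genes (0.00688 and 0.0201) passed with DESeq2 and with no filter, and fatty acid oxidation with edgeR on 8 libraries (0.0326). By limma, 9205 of 17837 genes changed with AS1949490, of which 5727 rose and 3478 fell. Of the genes tested, 1.97% rose and 0.835% fell at least 2-fold, and 5 genes rose and 7 fell at least 4-fold. The balance of directions depended on scaling, since 62.2% of calls were rises with library totals, 50.4% with TMM (4640 rose and 4562 fell) and 48.1% with RLE (4440 and 4786). Camera called 8 lists higher and 14 lower, of which 2 kept their call with an estimated correlation.

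Genes changed by both inhibitors mostly moved the same way. Of 6874 genes called with both, 3617 rose and 2364 fell with both, together 5981 (87%), where independent lists of these sizes would share 2050.4 and 1062.9. Opposite calls numbered 325 (higher with K149, lower with AS1949490) and 568 (the reverse), where independent lists would share 1245.2 and 1750.2. The 2 comparisons share no library, but both use 1 estimate of spread per gene. Their calls are therefore not fully independent, and the counts for independent lists serve only as a reference. Genes rising with both and named by rule were ASNS, DDIT4, PSAT1, ALDH1L2 and SEL1L3 (K149 log2 folds 2.45, 1.15, 0.96, 2.46 and 1.68, AS1949490 1.90, 1.74, 1.51, 3.14 and 1.56), of which ASNS and DDIT4 are uncertain. Genes falling with both were DIO2, FST, MCM2, TYMS and HMGB2 (K149 -1.30, -2.45, -3.86, -4.26 and -3.03, AS1949490 -1.98, -2.49, -1.06, -1.15 and -1.13), of which TYMS is uncertain. GADD45B, CYR61, CSRNP1, TUFT1 and CTGF rose with K149 and fell with AS1949490, by 0.85 and -1.55 for GADD45B and by 0.81 and -0.80 for CSRNP1. S100A14 (-1.24 and 0.90), MME (-0.97 and 1.16), TRIM29 (-0.70 and 0.77), ACKR3 (-1.36 and 1.37) and ZNF385A (-0.80 and 0.81) fell with K149 and rose with AS1949490.

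Across the 17837 genes, which are not independent replicates, the log2 folds had a Pearson correlation of 0.545 and a Spearman correlation of 0.564, with a slope of AS1949490 on K149 of 0.338. Without the 82 genes of the cell-cycle lists the Pearson correlation was 0.538. Leaving out so few genes could hardly move it, so this value cannot show whether the correlation rests on the cell cycle. With DESeq2 folds over all 38068 genes with reads the correlation was 0.188. Genes called higher by K149 in its own arm (6532) had a median log2 fold of 0.32 with AS1949490 (camera adjusted p = 4.87e-26, 0.000664 with an estimated correlation), and those called lower (5518) a median of -0.19 (4.64e-27, 0.000483 estimated). Of the 200 genes with the smallest p in each direction, 93% of those that rose and 100% of those that fell with K149 had the same sign with AS1949490, with medians of 0.66 and -0.71. For comparison, 57.8% of all genes tested had a positive fold with AS1949490 (median 0.079), a balance that depends on scaling.

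**Figure D3:**
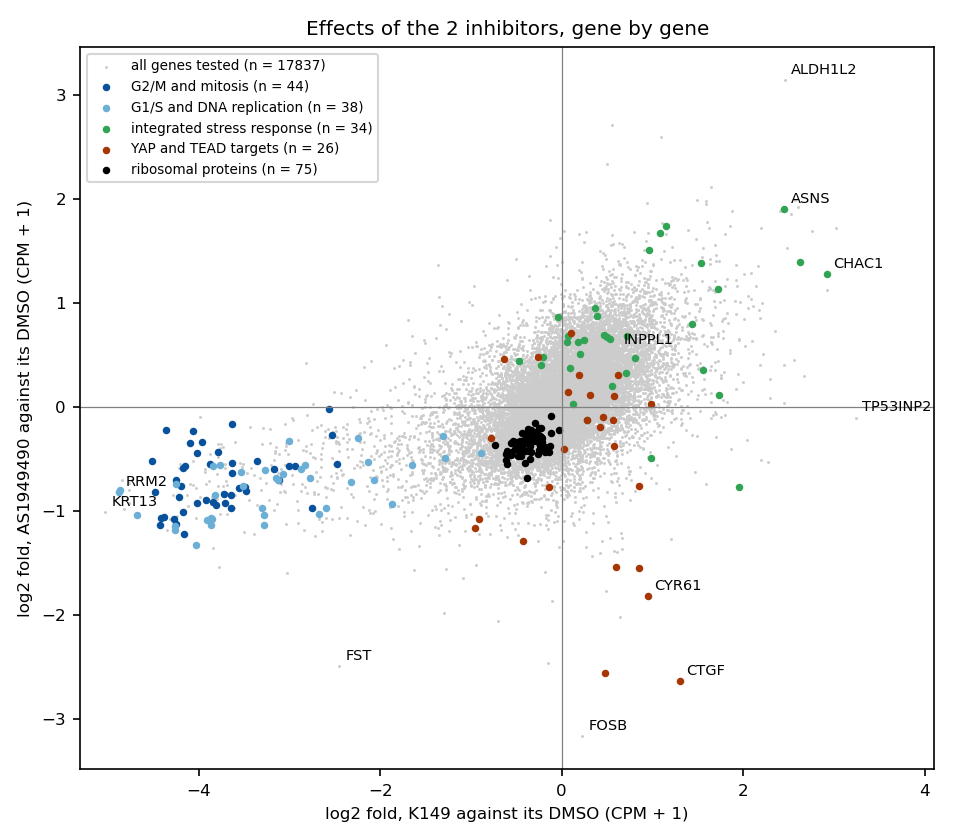
Log2 fold of each of 17837 genes with K149 (x axis) and AS1949490 (y axis), on the log2(CPM + 1) scale, with members of 5 lists coloured. Cell-cycle genes lay far left and moderately below 0, integrated stress response genes lay mostly in the upper right, and CTGF and CYR61 lay in the lower right.

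The effects of K149 and AS1949490, given at different doses, differed for 7207 genes by limma's test of the difference, with K149 above AS1949490 for 2699 and below for 4508. All 893 genes with opposite calls differed by this test, which 2 opposite calls with 1 shared spread per gene all but ensure. Of the 5981 with the same direction, 2025 differed, 1544 of them with the larger effect in K149. All 38 G1/S and all 44 G2/M genes fell further with K149 (median difference -2.45 and -3.10, camera adjusted p = 2.18e-31 and 4.34e-40), and both calls held with an estimated correlation (0.00251 and 0.0221). The largest negative differences were in TOP2A (-4.14 ± 0.14), MCM10 (-4.06 ± 0.15), RRM2 (-4.06 ± 0.09), KRT13 (-4.01 ± 0.21) and DLGAP5 (-3.99 ± 0.12). TOP2A fell from 528.1 ± 13.9 to 24.72 ± 0.852 CPM with K149 and was at 263.2 ± 59.3 and 223.6 ± 19.4 CPM in the other arm, without a call (adjusted p = 0.114). KRT13 started from 3.398 ± 0.566 CPM in the DMSO libraries of the AS1949490 arm. The largest positive differences were in CTGF (3.94 ± 0.24), FOSB (3.39 ± 0.24), TP53INP2 (3.35 ± 0.13), ANKRD1 (3.03 ± 0.17) and PTHLH (2.8 ± 0.17). TP53INP2 had no call with AS1949490 (-0.10 ± 0.10, adjusted p = 0.427). FOSB had no call with K149 (0.22 ± 0.15, limma adjusted p = 0.207) and was low in that arm, at 1.116 ± 0.236 and 1.465 ± 0.225 CPM.

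Camera called 17 lists for the difference, of which the other 15 lost their call with an estimated correlation. Above 0 (K149 over AS1949490) were the TGF-beta response (median 0.86, 21 of 27 genes higher and 1 lower, adjusted p = 3.01e-12, 0.108 estimated), immediate early genes (0.63, 22 of 26 higher, 4.15e-12, 0.108), YAP and TEAD targets (0.51, 15 higher and 4 lower of 26, 7.58e-06, 0.31) and autophagy (0.38, 7.58e-06, 0.158). FOXO targets (0.62, adjusted p = 1.64e-05, 0.193 estimated), histones (0.51, 0.00124, 0.108), the unfolded protein response (0.19, 0.00157, 0.193), lysosomes (0.21, 0.0032, 0.242), MAPK-ERK output (0.35, 0.00479, 0.31), mitochondrially encoded genes (0.28, 0.00636, 0.547) and NRF2 targets (0.10, 0.03, 0.637) were also above 0. MYC targets (-0.47, adjusted p = 2.96e-05, 0.232 estimated), interferon-stimulated genes (-0.35, 0.00962, 0.193), fatty acid synthesis (-0.48, 0.00995, 0.334) and squamous differentiation (-0.37, 0.031, 0.319) were below 0. The integrated stress response had a median difference of -0.14, with 12 genes higher and 15 lower (adjusted p = 0.672, camera's direction higher). Ribosomal protein genes had a median difference of -0.05 (adjusted p = 0.554), which was 0.067 and called higher without DMSO replicate 2 of the AS1949490 arm (0.00321). Without that library oxidative phosphorylation was likewise called higher (median 0.171, adjusted p = 0.00424). AHR targets (median 0.46, adjusted p = 0.0588) passed without DMSO replicate 3 of the K149 arm or AS1949490 replicate 2 (0.0408 and 0.0462), and with DESeq2 (0.0465), edgeR (0.0374, and 0.0311 on 8 libraries) or a pseudocount of 0.1 (0.0357). Their median was 0.274 without DMSO replicate 2 of the AS1949490 arm and 0.143 with no filter, with no call (0.0681 and 0.0606). NF-kB genes (0.37, adjusted p = 0.0588) passed without AS1949490 replicate 2 (0.0399) and with a pseudocount of 5 (0.0461). With DESeq2, p53 targets (0.0178), matrix proteases (0.0458) and hypoxia genes (0.0122) passed, and p53 targets also with edgeR on 8 libraries (0.0185). With no filter, heat shock (0.00579), hypoxia genes (0.0121) and fatty acid oxidation (0.0488) passed. The NRF2 call was lost without K149 replicate 2 (0.0514), DMSO replicate 2 of its arm (0.102), DMSO replicate 1 of the AS1949490 arm (0.115) or AS1949490 replicate 1 (0.0879), and its median was 0.047 without K149 replicate 2, and in the AS1949490 arm 0.055 and 0.171 without DMSO replicate 1 or 2 and 0.167 without AS1949490 replicate 2. The MAPK-ERK median was 0.232 without DMSO replicate 2 of the AS1949490 arm. The squamous call was lost without DMSO replicate 2 of the AS1949490 arm (0.0737) or AS1949490 replicate 1 (0.0682) and with a pseudocount of 0.1 (0.0633), and the histone call with DESeq2 (0.0966) and with edgeR on 8 libraries (0.0594).

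**Figure D4:**
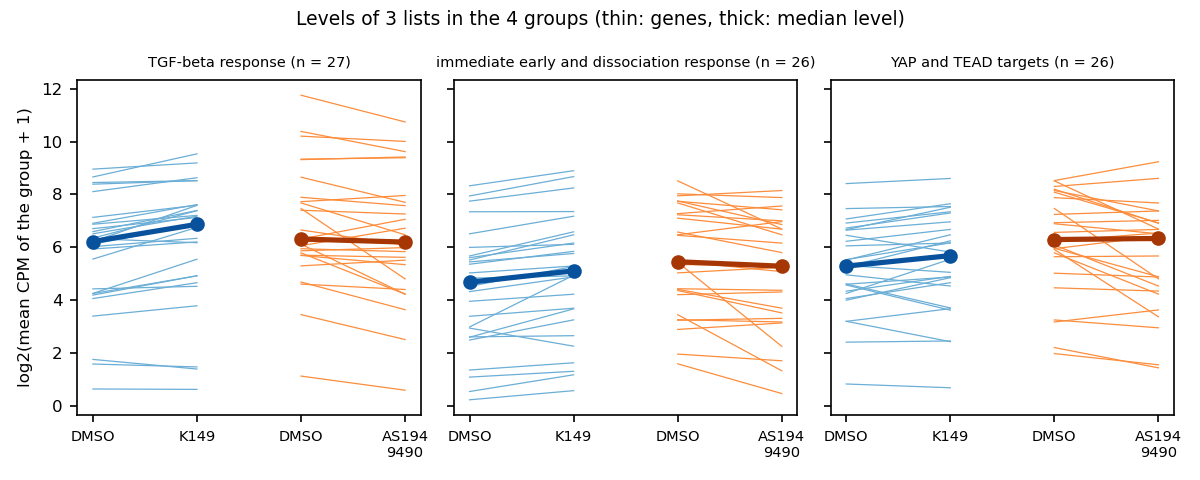
Levels of the TGF-beta response (27 genes), immediate early (26 genes) and YAP and TEAD (26 genes) lists in the 4 groups, as log2(mean CPM of the group + 1) on the y axis, with thin lines for genes and thick lines for the median level. Lines run from DMSO to inhibitor within each arm (blue K149, orange AS1949490). Many genes that rose with K149 started lower in the DMSO libraries of that arm, and the median level of a list can move otherwise than the median of its folds, as for YAP and TEAD targets with AS1949490.

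Between the DMSO libraries of the 2 arms, limma called 11809 genes, 6615 higher in the K149 arm and 5194 higher in the AS1949490 arm. Of 28 NF-kB and cytokine genes, 21 were lower and 3 higher in the K149-arm DMSO libraries (median log2 difference -1.25, camera adjusted p = 1.97e-07, 0.0266 with an estimated correlation), the 1 list that kept its call. Its median ran from -2.218 (edgeR, 8 libraries) to -0.602 (no filter). Immediate early genes (-0.99, 20 of 26 lower), TGF-beta response (-1.17, 17 of 27), YAP and TEAD targets (-0.68, 16 of 26) and MAPK-ERK output (-0.94, 20 of 27) were lower there, with adjusted p of 6.35e-06, 0.000215, 3e-05 and 6.86e-07, and 0.233, 0.322, 0.326 and 0.156 estimated. Cholesterol synthesis (0.87, 22 of 25 higher) and interferon-stimulated genes (0.58, 27 of 37 higher) were higher there, with adjusted p of 3.25e-06 and 4.18e-05, and 0.287 and 0.0909 estimated. The cell-cycle lists were not called (G2/M median 0.22, adjusted p = 0.0772; G1/S -0.10, adjusted p = 0.292). The labels give no batch, and a batch and the arm cannot be told apart in this contrast.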

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

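The tests of scaling, of starting level and of treated levels in the first 2 patterns were chosen only after the results were seen. So was that of exon length alone in the third. The tests of exon length with abundance and of other splits were planned before. The effects of K149 and AS1949490 differed by the test of the difference for 7207 genes and 17 lists, at doses that were not matched. With an estimated correlation camera called 2 of these lists, those of the cell cycle, and the other 15 lost their calls (adjusted p = 0.108 to 0.637). Positive values are effects of K149 above those of AS1949490.

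The cell-cycle lists fell further with K149, by -3.10 (G2/M, 44 genes) and -2.45 (G1/S, 38 genes) on the log2 scale, as did TOP2A (-4.14), MCM10 (-4.06), RRM2 (-4.06) and DLGAP5 (-3.99). A scaling of the libraries would move all genes alike and leave the 82 cell-cycle genes level with the median of all genes. They lay at -2.75 from it (-2.79 to -2.72 without each library). The lists were flagged because camera set them apart from other genes, so this value adds no separate evidence on scaling. A lower start in the AS1949490 arm would need a positive difference of over 1.5 between the DMSO sets, which was 0.07 at the median of these genes. Dose, the compound and a difference between the cells of the arms stay open and were not tested.

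The TGF-beta, immediate early and YAP lists had median differences of 0.86, 0.63 and 0.51, with CTGF (3.94), FOSB (3.39) and ANKRD1 (3.03) among their members, but lost their calls with an estimated correlation (adjusted p = 0.108, 0.108 and 0.31), and the YAP list was not called with K149 (0.135). FOSB was low in the K149 arm (1.116 CPM in DMSO, 1.465 with K149, no call), so its difference came mostly from its fall with AS1949490. Scaling moves all genes alike and would leave the 75 members level with the median of all genes. They lay 0.68 above it (0.62 to 0.75 without each library). These lists, too, were flagged because camera set them apart from other genes, so this value adds no separate evidence on scaling. If only the DMSO libraries of the AS1949490 arm stood apart, treated libraries of both arms would lie at 1 level: their median difference was -0.05, as that explanation predicts, against -0.66 between the DMSO sets, with 40 members lower and 35 not lower in K149 libraries. A slope test, added after that median was seen, goes against treated libraries lying at 1 level gene by gene, with a slope of 0.61 (0.58 to 0.63 without each library) of the treated on the DMSO difference, though the slope over all genes was no lower (0.69). Treated libraries near 1 level at the median are also what DMSO libraries of the K149 arm standing apart would give. A state of the DMSO cells of either arm may therefore account for part of the difference in these lists. Such a state cannot be told apart from an effect of the inhibitors. Of these lists, YAP had no established rise with K149.

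Camera called the ribosomal protein list lower with both inhibitors, and lost both calls with an estimated correlation (adjusted p = 0.632 with K149 and 0.497 with AS1949490). The list was set against 1000 random sets of genes matched on length and abundance. Median length was 3248 and 3245 bases for the sets and 3109 for the ribosomal genes. The list's median log2 fold was -0.36 with K149 and -0.33 with AS1949490. It lay at -0.30 and -0.26 from the median of the matched sets, and no set was as low in either. The bound set for this test, more than 0.1 below the lowest set, was missed with K149 (-0.05) and met with AS1949490 (-0.13), but not without DMSO replicate 1 of that arm (-0.04, where the list's median was -0.208), so length together with abundance stays open for both. Length here is that of the merged exons of all annotated transcripts of a gene, which can differ from that of the transcripts expressed. Removing the trend of fold with this length left medians of -0.34 with K149 and -0.39 with AS1949490 (-0.33 and -0.28 at the nearest to 0 without 1 library). Camera still called the list (adjusted p = 0.00243 and 1.41e-10), which goes against merged exon length alone as the whole cause. The length of the expressed transcripts was not measured, so its part stays open.

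In the K149 arm, of the 10 splits of the 6 libraries only the real one gave as many as 11837 genes. The highest other gave 0 by limma, with 85 to 369 genes at an unadjusted p under 0.05 against 12350. For lists, 3 of the 10 splits, the real one included, gave 16 or more, and the highest other gave 17. Every other split has K149 and DMSO libraries on both sides. Part of the K149 effect then stays between its groups and the rest adds to their spread. These splits therefore cannot show what chance gives, and they are too few for a share under 0.05.

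The other lists whose effects differed at the preset correlation, none of them with an estimated one, were autophagy (0.38), FOXO targets (0.62), histones (0.51), the unfolded protein response (0.19), lysosomes (0.21), MAPK-ERK output (0.35), mitochondrially encoded genes (0.28) and NRF2 targets (0.10), with K149 above. MYC targets (-0.47), interferon-stimulated genes (-0.35), fatty acid synthesis (-0.48) and squamous differentiation (-0.37) had K149 below. The other genes were TP53INP2 (3.35) and PTHLH (2.8), with K149 above, and KRT13 (-4.01), with K149 below.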

How the results depend on the processing

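Each result was computed again under the alternatives; edgeR and the crossed replicate block were added after the data were seen. Of the named gene values, 5606 kept their direction and side of the threshold and 0 did not. These values count each gene once per alternative. Most of the genes were chosen for large folds or small p-values, so this says little about other genes. Of the counts and other main values, 535 stayed and 13 moved, where counts stayed if within 1.5 times, the correlation of folds if within its SD over pairs of treated libraries (0.045), and tested values if on the same side of the threshold in the same direction. The correlation (0.545) moved to 0.188 (DESeq2), 0.49 (edgeR) and 0.416 (edgeR, 8 libraries), and the cause was not tested. Of list values, 3124 stayed, 42 lost and 53 gained their call, and 70 changed camera's direction. Under alternatives that left out no library, the median moved by over 1.5 times or changed sign for 1 of 16 lists called with K149, 11 of 22 with AS1949490, 3 of 17 for the difference and 7 of 18 between the DMSO sets. Genes changed ranged from 10851 to 12296 with K149 and from 6884 to 9737 with AS1949490, and INPPL1 from 0.522 to 0.653 and from 0.441 to 0.605. A left-out library of the AS1949490 arm leaves 1 in its group, which is assumed to vary like the other groups. At this depth values under 1 CPM rest on few reads.

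With an estimated correlation camera called 3 (K149), 2 (AS1949490), 2 (difference) and 1 (DMSO sets) lists. Fry, which does not compare lists with other genes, called 34 (K149), 31 (AS1949490), 26 (difference) and 33 (DMSO sets). DESeq2 called 30 lists between the DMSO sets. EdgeR with 8 libraries called 3593 genes higher with AS1949490 and 2384 higher with both, where test, scaling and libraries changed at once; edgeR with all 10 called 4528 higher with AS1949490, and limma with TMM 4640.

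Camera's direction changed for lists that were not called, and for the called AS1949490 histones with no filter (median -0.034). Medians follow, and the cause was not tested. With AS1949490, FOXO targets had 0.064 (pseudocount 5), 0.082 (no filter), 0.002 (TMM), -0.016 (RLE), 0.028 (upper quartile) and -0.012 (edgeR), and -0.006 to 0.17 without 1 library. Antigen presentation had 0.057 (pseudocount 5), 0.058 (no filter, and crossed replicate block) and 0.035 (edgeR, 8 libraries), and -0.016 to 0.12 without 1 library. Squamous differentiation had 0.178 (stricter filter), 0.071 (TMM), 0.055 (RLE), 0.095 (upper quartile), 0.099 (edgeR, 8 libraries) and 0.144 (crossed block), and 0.006 to 0.215 without 1 library. Immune markers had -0.005 (arm alone) and -0.036 to 0.025 without 1 library, and apoptosis regulators 0.024 (DESeq2). With K149, nuclear-retained RNA had 0.113 (no filter), 0.002 (TMM), 0.004 (RLE), 0.008 (upper quartile), 0.015 (replicate block, and crossed block), 0.218 (edgeR) and 0.491 (edgeR, 8 libraries), and -0.029 to 0.196 without 1 library. Mitochondrially encoded genes had -0.103 to 0.035 without 1 library. For the difference with no filter, medians were -0.036 (phosphoinositide enzymes), -0.053 (integrated stress response), -0.047 (ribosomal proteins), -0.192 (EGFR family) and -0.046 (columnar markers). Cholesterol synthesis had -0.134 (TMM), -0.109 (RLE), -0.145 (upper quartile), -0.119 (DESeq2), -0.131 (edgeR) and -0.077 (edgeR, 8 libraries). Proteasome had -0.018 (TMM), 0.008 (RLE), -0.03 (upper quartile), -0.004 (DESeq2) and -0.013 (edgeR), senescence factors 0.098 (DESeq2) and ribosomal proteins -0.081 (edgeR, 8 libraries). Without 1 library the differences were -0.058 to 0.01 (phosphoinositide enzymes), -0.154 to 0.067 (ribosomal proteins), -0.244 to -0.141 (EGFR family), -0.244 to -0.14 (cholesterol), -0.164 to 0.02 (proteasome) and -0.092 to 0.171 (oxidative phosphorylation).

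Same-numbered libraries had residual correlations of 0.1, 0.05 and -0.01 in the K149 arm and -0.24 and -0.24 in the AS1949490 arm, so the numbers were not taken to pair them. With a replicate block limma called 11479 genes with K149, 8579 with AS1949490 and 6408 for the difference, and camera lost the AHR call with K149 (adjusted p = 0.0633) and gained NF-kB for the difference (0.0492), with no other list call changed. The crossed replicate block gave 12122 and 9534 genes and 15 and 19 lists with the inhibitors.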

Other observations

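The genes named here were chosen after their values were seen, and no explanation was tested for them. The 8 genes taken in each direction between the DMSO libraries of the arms were not tested for a common theme. KRT13, a keratin of stratified epithelium, had 415.2 ± 3.78 CPM in the DMSO libraries of the K149 arm (SD, n = 3) and 3.398 ± 0.566 CPM in those of the AS1949490 arm (SD, n = 2), a log2 difference of 6.57 ± 0.15. The sodium channel subunit SCNN1A had 482.2 ± 2.85 and 8.844 ± 0.709 CPM, and the bladder epithelium gene UPK1B (5.70 ± 0.14) and PSCA (5.53 ± 0.14) lay the same way. The cytokine IL11 had 1.132 ± 0.153 and 50.24 ± 0.803 CPM, a log2 difference of -4.59 ± 0.10, and the activin subunit INHBA (-4.51 ± 0.16), IL1A (-4.15 ± 0.13) and PTHLH (-4.10 ± 0.12) were also higher in the AS1949490 arm. The others were CES1, DAPK1, PPFIBP2 and CRAT (5.63 to 4.45), higher in the K149 arm, and FOSB, CGB8, SGK1 and TMEM200A (-4.33 to -3.92), higher in the AS1949490 arm.

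Further lists called between the DMSO sets were lower in the K149 arm for MYC targets (median -0.41, camera adjusted p = 2.43e-08), matrix proteases (-0.50, 3.25e-06), the integrated stress response (-0.45, 0.00029), proteasome (-0.25, 0.000993), mesenchymal genes (-0.90, 0.00119), ribosomal proteins (-0.11, 0.00451), senescence factors (-1.14, 0.00516) and basal squamous genes (-0.24, 0.0218). They were higher there for LXR targets (1.03, adjusted p = 0.00346), fatty acid synthesis (0.55, 0.00359) and squamous differentiation (0.92, 0.0437). None of these 11 kept its call with an estimated correlation (lowest adjusted p = 0.0768). The ribosomal call was lost without DMSO replicate 1 of the AS1949490 arm (median 0, adjusted p = 0.463) and with edgeR on 8 libraries (0.257), its median was -0.231 without DMSO replicate 2, and the proteasome median was -0.124 without replicate 1. Without DMSO replicate 2 of that arm the basal and squamous calls were lost (0.0732 and 0.0843), the latter also with a pseudocount of 0.1 (0.0526).

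Interferon-stimulated genes went both ways with K149, where 11 of 37 rose and 16 fell and camera did not call the list (median -0.09, adjusted p = 0.427). Those that fell included OAS3, from 143.6 ± 4.87 to 46.0 ± 3.76 CPM (SD, n = 3 each, log2 fold -1.62 ± 0.06), and IFIT1 (-1.43 ± 0.09). IFI35 and SAMD9L rose with both inhibitors, by 0.68 ± 0.08 and 0.44 ± 0.08 with K149 and 1.43 ± 0.10 and 1.36 ± 0.10 with AS1949490. The EGFR ligand AREG rose with K149 (1.7 ± 0.09) from 3.515 ± 0.293 CPM, and was at 65.31 ± 2.67 CPM in the DMSO libraries of the AS1949490 arm, where its log2 fold was -0.07 ± 0.11 without a call.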
